A study of Drosophila melanogaster with 2 samples.

How the data were processed

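Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole embryos of Drosophila melanogaster of both sexes, 0 to 24 h old, from a transgenic line that carries the kinase gene nmo fused at its C-terminus to green fluorescent protein. Chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an antibody against the tag, per the labels. The series forms 1 group of 2 samples, biological replicates 2 and 3, which the labels list as separate biosamples. No comparison between groups is implied by the labels, and no input or mock precipitation was analysed here.

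The authors deposited 4 peak lists in narrowPeak format on genome assembly dm6. Replicate 2, replicate 3 and the pool of both each had a list of exactly 30000 peaks, called per the deposited text notes on the alignments together with 1 further file that also entered the control-normalised tracks. The authors also deposited a list thresholded by the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between replicates, with 9299 peaks. All 9299 had identical entries in the pooled list, where they held ranks 1 to 9299 by signal value. The aligner, the peak caller, its settings and the IDR threshold were not given in the sources used here. Column 7 of the deposited lists holds a signal value per peak on a scale set by the authors' peak caller, and it was used only to rank and compare peaks within a list. Column 9 of the deposited lists holds the −log10 q-value, which reached its maximum of 4.27 in 9232 of the 9299 IDR peaks and fell to 0.167 in the pooled list. It was not used for ranking. Read depth was unknown, so intervals on shares cover only the counting of peaks or genes.

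Genes, transcripts and their transcription start sites (TSSs) came from Ensembl release 115 (BDGP 6.54), from which 5889 transposable-element entries were taken out, leaving 18277 genes, 13968 of them protein-coding. Sequence came from the RefSeq copy of assembly Release 6, whose coordinates are those of dm6. No peak lay beyond a chromosome end and none was on a sequence outside chromosomes 2L, 2R, 3L, 3R, 4, X and Y. Coordinates are given 1-based.

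Each summit was given to the first matching class among: within 500 bp of a TSS of a protein-coding gene, within 500 bp of a TSS of another gene, 5' UTR, 3' UTR, coding sequence, intron, other exon, and intergenic. Shares were compared with 1000 random placements on the same chromosomes (200 for the alternatives, except placements matched on GC content, also 1000) by a two-sided permutation test. A gene was counted as having a summit when an IDR summit lay within 1000 bp of one of its TSSs. For 19 gene lists, membership was tested against all 13968 protein-coding genes by a two-sided Fisher's exact test. For 29 consensus sequences, presence in the 201 bp around a summit was compared with a window 1000 bp away from the same summit, on a randomly drawn side, by an exact McNemar test. Median signal values were compared by a permutation test with 100000 resamples. Replicate overlap needed at least 1 bp and was set beside 100 circular shifts of 1 list along its chromosomes. Peak counts around nmo were set beside 10000 random windows of the same length; the condition that these hold at least as many TSSs was added to the design. Tests of genomic classes, gene lists and consensus sequences were adjusted within each family by the Benjamini-Hochberg method. The threshold was 0.05 on the adjusted p. The p-values given for other gene types, transfer RNA genes, short sequences shared by summits away from promoters, the X chromosome and peak strength were not adjusted. Peaks and genes are not independent replicates, so these tests describe this set of peaks.

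Gene lists, consensus sequences, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took nmo, the genes nearest to the 15 strongest IDR peaks, the 2 members of each list with the strongest summit (4 for lists past the threshold), and up to 2 members of each signalling list without a summit, in list order; 1 gene that the rule takes is not reported here. Some symbols of the fixed lists were not in the annotation and were dropped, among them Dl, Dfz2, th, h and d. The pattern that collected chorion genes by symbol also took Cp190 and Cp110, which are not chorion genes. The alternatives were the strongest 9299 peaks of each replicate alone, the 4649 IDR peaks with the highest signal value, other distances, other overlap criteria, and 10000 gene sets matched on gene length and TSS number (3 or more TSSs as 1 class). Others were a window of 50 bp on each side for motifs, a control window 3000 bp away, and summits over 1000 bp from a TSS. Controls matched on GC content, gene lists with all pooled peaks, the comparison of divergent genes with other genes that had a close neighbour, and the chorion list without Cp190 and Cp110 were added after the data were examined.

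The tests were tried on simulated data. Among the 13968 genes, lists of 200 genes planted with odds ratios of 3 and 6 gave median estimates of 3.05 and 6.00 in 200 simulations each, all called, and lists without an effect were called in 8 of 200. When summits were placed at TSSs, so that neighbouring genes also gained them, the medians were 2.57 and 5.25, and lists without an effect were called in 2 of 20. Calls in these simulations were made on the unadjusted p. The 19 lists tested held 14 to 179 genes, so these simulations do not give the power of their tests. Where having a summit depended on TSS number alone, the unmatched test called 20 of 20 lists of genes with many TSSs and the matched sets called 0. The planted dependence stopped rising at 3 TSSs, as the matching does, so effects of TSS number above 3 were not tried. A sequence planted in 10% of the 9299 windows was recovered at 10.0%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.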

Results

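The peak lists describe where chromatin from 0 to 24 h fly embryos was recovered with GFP-tagged Nemo. Nemo, the product of nmo, is a proline-directed serine/threonine kinase of the Nemo-like kinase family, known from planar cell polarity, Wnt and BMP signalling and the circadian clock. The design has 1 group with 2 biological replicates and no comparison between groups. The IDR list held 9299 peaks with a median width of 428 bp (range 109 to 896 bp), which together covered 3135 kb. Their signal values ran from 166 to 7478 with a median of 333.

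The strongest peaks lay at the promoters of genes of varied function. The peak with the highest signal value (7478) had its summit at position 11197301 of chromosome 3R, -291 bp from a TSS of cu, which encodes Nocturnin, and ranked 1 in replicate 2 and 2 in replicate 3. The next was at CG14100 on 3L (summit 19590613, -89 bp from the TSS, signal value 7400). Among the 15 strongest, 12 summits lay within 500 bp of a protein-coding TSS, and 3 lay in introns, those nearest to cbt, CG11050 and Trl. Several of these genes encode chromatin proteins: Chro, the interband protein Chromator (signal value 5851), Trl, the GAGA factor (5037), and ph-p, a Polycomb-group protein (5032). Others encode proteins of other kinds, such as the UDP-galactose transporter Ugalt (6603), the mitochondrial ribosomal protein mRpL41 (5798), the arginine methyltransferase Art3 (6107) and PNPase (4986). The remaining members were px (5465), CG18549 (5181), CG9147 (4981) and CG5611 (4881). For 7 of the 15 summits another gene had a TSS within 1000 bp, so the assignment is not unique: eIF2Bbeta beside Ugalt, mRpS10 beside Art3, Ssl1 beside Chro, CG8079 beside mRpL41, Gprk2 beside PNPase, Fbw5 beside CG9147 and Mtl beside CG5611. All 15 ranked between 1 and 18 in each replicate.

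The replicates found largely the same places. Of the 9299 strongest peaks of replicate 2, 86.4% (95% Wilson interval 85.7 to 87.1) overlapped 1 of the 9299 strongest of replicate 3, against a mean of 4.80% after shifting the list. In the other direction the share was 82.2% (81.4 to 82.9) against 4.73%. The 1000 strongest peaks of each replicate were all overlapped by a peak of the other's full list. The IDR list was thresholded on agreement between replicates, and its members are the 9299 strongest pooled peaks. Of these, 97.2% were overlapped in both replicates' lists, and the signal values of the replicates had a Spearman's rho of 0.83 across 9038 peaks. Over the 22722 replicate 2 peaks overlapped by a replicate 3 peak, a set not drawn from the pooled list, it was 0.73. With summits required to lie within 100 bp of each other the overlap was 77.4% in both directions, and with a reciprocal overlap of 50% it was 64.8% and 62.9%.

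Nemo peaks were concentrated at promoters and almost absent from coding sequence. Of the 9299 summits, 4592 (49.4%) lay within 500 bp of a protein-coding TSS, 4.3 times the 11.5% ± 0.340 (SD of 1000 placements) of random positions. Introns held 31.1% against 39.6% and intergenic sequence 15.1% against 27.1%. Only 8 summits lay in coding sequence (0.0860% against 13.1%), and 3' UTRs (0.806% against 5.06%) and 5' UTRs beyond 500 bp of a TSS (0.323% against 0.783%) were also below random. Each of these 6 differences had an adjusted p of 0.0013 in the permutation test, from the smallest p that the placements allow. Summits near TSSs of other gene types were close to random (2.42% against 2.10%, adjusted permutation p = 0.048), a difference that did not pass the threshold under any of the 5 alternatives, and other exons did not differ (adjusted p = 1).

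**Figure D1:**
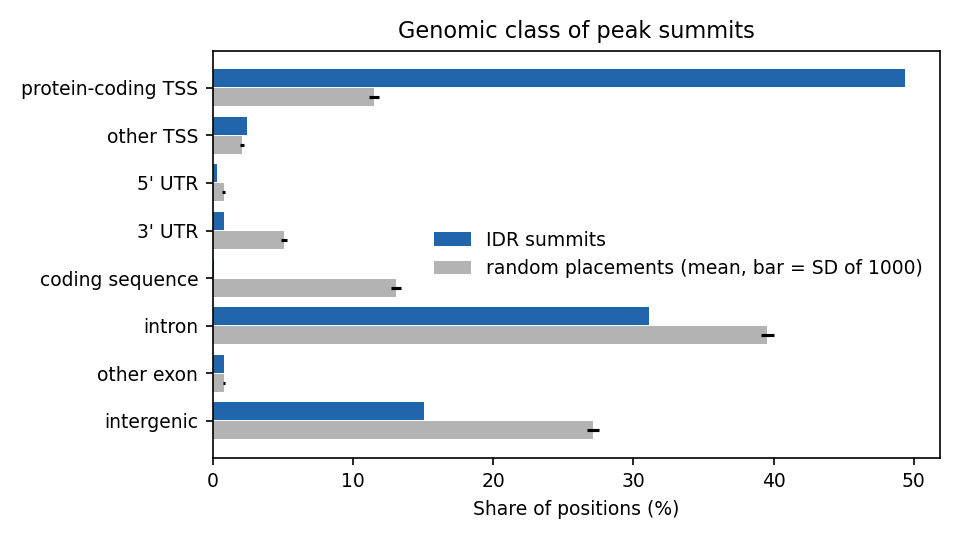
Share of positions (%) in each genomic class, for the 9299 IDR summits (blue) and for random placements on the same chromosomes (grey, mean of 1000, error bar SD). Protein-coding TSSs held 49.4% of summits against 11.5% of random positions, and coding sequence 0.0860% against 13.1%.

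Summits sat just upstream of the start site. The 4817 summits within 500 bp of any TSS had a median position of -91 bp (quartiles -175 and -21 bp), and 82.3% of them (95% Wilson interval 81.1 to 83.3) were upstream. Within 100 bp of a TSS lay 24.1% of all summits against 3.33% of random positions, and within 1000 bp 60.4% against 23.6%. The strongest peaks of replicate 2 were upstream less often (74.9%, median -71 bp) than those of replicate 3 (84.2%, median -99 bp). Promoter peaks were modestly stronger than others, with a median log2 signal value of 8.50 against 8.25 (ratio 1.18, Cliff's delta 0.129, permutation p = 1e-05, the smallest the test can give), but not detectably so among the 4649 strongest peaks (delta 0.0359, permutation p = 0.15).

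**Figure D2:**
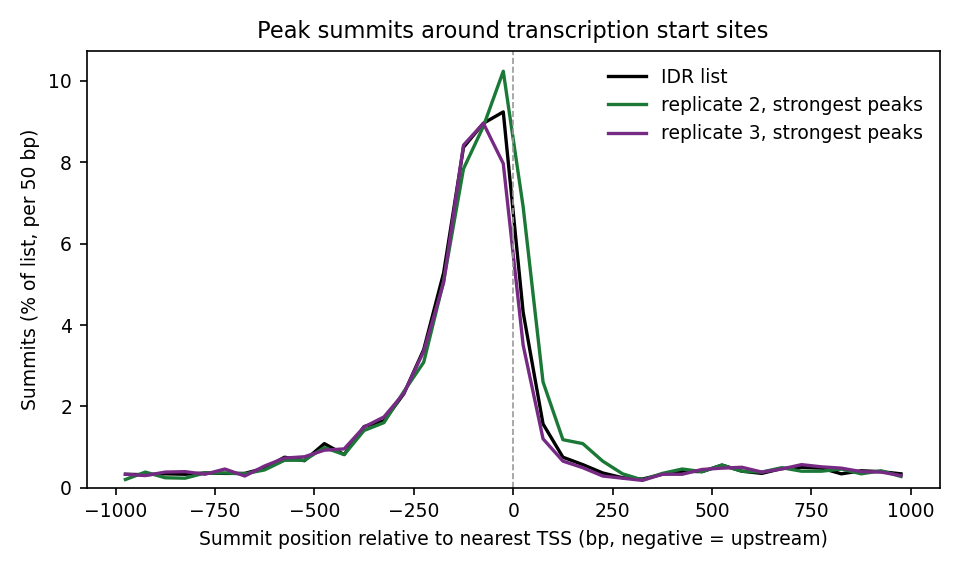
Summits per 50 bp (% of each list of 9299 peaks) by position relative to the nearest TSS (bp, negative is upstream), for the IDR list (black) and the strongest peaks of replicate 2 (green) and replicate 3 (purple). All 3 lists peak upstream of the TSS, with replicate 2 extending further downstream.

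Ribosomal protein genes and several signalling pathways had Nemo peaks at their promoters more often than other genes. Chemoreceptor and cuticle genes had them less often. Genes were not matched on expression and no mock precipitation was analysed, so these shares need not be particular to Nemo. Over all protein-coding genes, 6122 of 13968 (43.8%) had a summit within 1000 bp of a TSS. Of 19 lists, 6 had a higher share and 4 a lower share by Fisher's exact test. The 4 lower lists include histone genes, repeated copies in which reads cannot be placed with certainty. Cytoplasmic ribosomal protein genes were highest, with 81 of 85 (95.3%, odds ratio 26.3, 95% interval 9.87 to 98.8, exact adjusted p = 9.7e-24). Strong peaks lay at RpS27 (signal value 1648), RpL32 (1455) and RpL34b (1365), with summits between -124 and -67 bp of a TSS.

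Among the signalling lists, hedgehog and Hippo genes had summits in 25 of 31 cases (80.6%, odds ratio 5.36, interval 2.14 to 16.0, exact adjusted p = 0.00014). The strongest peaks were at CycE, the cyclin of S-phase entry (1972), and yki, the transcriptional coactivator of the Hippo pathway (1111). Next came the protocadherin gene ds (994) and Mer (771). The genes hh and ci had no IDR summit, but with all pooled peaks 31 of 31 genes of this list had a summit. EGFR and MAP kinase genes had summits in 31 of 40 cases (77.5%, odds ratio 4.43, interval 2.06 to 10.6, exact adjusted p = 8.7e-05), led by the kinase genes Mkk4 (3572) and p38a (3153), the EGFR ligand gene spi (2007) and edl (1839). The ligand genes grk and vn had no IDR summit. Notch pathway genes had summits in 22 of 31 cases (odds ratio 3.14, interval 1.39 to 7.75, exact adjusted p = 0.0074). The strongest were at E(spl)m3-HLH (2377), E(spl)m7-HLH (1909), numb (1642) and aph-1 (1422). Ser and H had no IDR summit, but with all pooled peaks 30 of 31 genes of this list had a summit. Among the 4649 strongest peaks the list did not pass the threshold (13 of 31, odds ratio 1.91, exact adjusted p = 0.18). Dl, the gene of the ligand Delta, is not in this count because its symbol was not in the annotation used.

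Planar cell polarity genes had summits in 15 of 19 cases (78.9%, odds ratio 4.82, interval 1.53 to 19.9, exact adjusted p = 0.0061), among them nmo itself (1171), app (995), ds and pk (775). Wnt genes had them in 23 of 35 cases (65.7%, odds ratio 2.46, interval 1.17 to 5.43, exact adjusted p = 0.019), led by gish, a casein kinase 1 gene (3644), Sox14 (2949), sgg, the GSK3 gene (1806), and gro, the corepressor gene (1509). The Wnt effector arm and the receptor fz had no IDR summit. Against gene sets matched on length and TSS number, the Wnt list (expected 56.1%, permutation adjusted p = 0.35) and the polarity list (expected 54.5%, permutation adjusted p = 0.053) were no longer past the threshold, but they were against sets matched on promoter GC content and TSS number (permutation adjusted p = 0.031 and 0.0014). In the replicate 3 list alone neither passed (Wnt odds ratio 1.82, exact adjusted p = 0.13; polarity 2.97, exact adjusted p = 0.058), nor did either among the 4649 strongest peaks (2.22, exact adjusted p = 0.052; 2.38, exact adjusted p = 0.14). BMP and activin genes did not pass the threshold (17 of 35, 48.6%, odds ratio 1.21, exact adjusted p = 0.73), but did in the replicate 2 list alone (24 of 35, odds ratio 2.71, exact adjusted p = 0.01) and with all pooled peaks (28 of 35, odds ratio 2.48, exact adjusted p = 0.042). IDR summits were found at brk (1784) and Mad (1606) in this list, and none at dpp or wit.

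Chemoreceptor genes, expressed in sensory neurons, had summits in 8 of 179 cases (4.47%, odds ratio 0.0587, interval 0.0249 to 0.118, exact adjusted p = 5.5e-32). Summits at Or88a (589), Gr32a (570), Or9a (414) and Gr63a (278) were all within 500 bp of a protein-coding TSS, which for the first 3 was that of another gene, since they lay 500 bp or more from their own. Epidermis and cuticle genes had summits in 4 of 31 cases (12.9%, odds ratio 0.189, interval 0.0481 to 0.544, exact adjusted p = 0.0012): tyn (611), grh (349), cyr (235) and Ddc (230). None of the 111 histone genes had one (exact adjusted p = 1.3e-27). These are near-identical repeated copies in which reads cannot be placed with certainty, so the test cannot tell missing peaks from unplaced reads. Of 14 genes collected as chorion and yolk genes, 1 had a summit (exact adjusted p = 0.011), and this was Cp190, an insulator protein gene (2817); without it and Cp110 the count was 0 of 12. The list did not pass the threshold in the replicate 3 list alone (2 of 14, exact adjusted p = 0.086) or among the 4649 strongest peaks (exact adjusted p = 0.21).

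The remaining lists did not pass the threshold in Fisher's test with the IDR list and a distance of 1000 bp. With summits within 500 bp, circadian clock genes (odds ratio 3.28, exact adjusted p = 0.029) and proteasome genes (1.95, exact adjusted p = 0.041) did pass it, and apoptosis genes did against sets matched on promoter GC content and TSS number (permutation adjusted p = 0.049). Summits were found at 9 of 27 eye genes (so 636, ro 610), 14 of 33 segmentation genes (H15 810, oc 481), 7 of 18 Hox and homeotic genes (Dfd 449, cad 365) and 15 of 43 neural fate genes (elav 2275, brat 1639). They were found at 17 of 42 mesoderm and muscle genes (Poxm 2233, tin 1478), 10 of 15 apoptosis genes (hid 1221, Diap1 940.3), 13 of 19 circadian clock genes (sgg and nmo strongest) and 27 of 48 proteasome genes (Prosalpha4 848, Rpn6 834). Apoptosis genes did pass it in each replicate alone (11 and 12 of 15, exact adjusted p = 0.043 and 0.012). With all pooled peaks, 46.2% of which had a q over 0.05, the segmentation, neural fate and mesoderm lists turned from odds ratios below 1 to 3.47, 3.19 and 3.10, each past the threshold. Against sets matched on length and TSS number the eye and mesoderm lists lay below expectation (permutation adjusted p = 0.046 each) and the proteasome list above it (0.029), but none of these 3 differences passed against sets matched on promoter GC content and TSS number (permutation adjusted p = 1, 0.86 and 0.26).

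**Figure D3:**
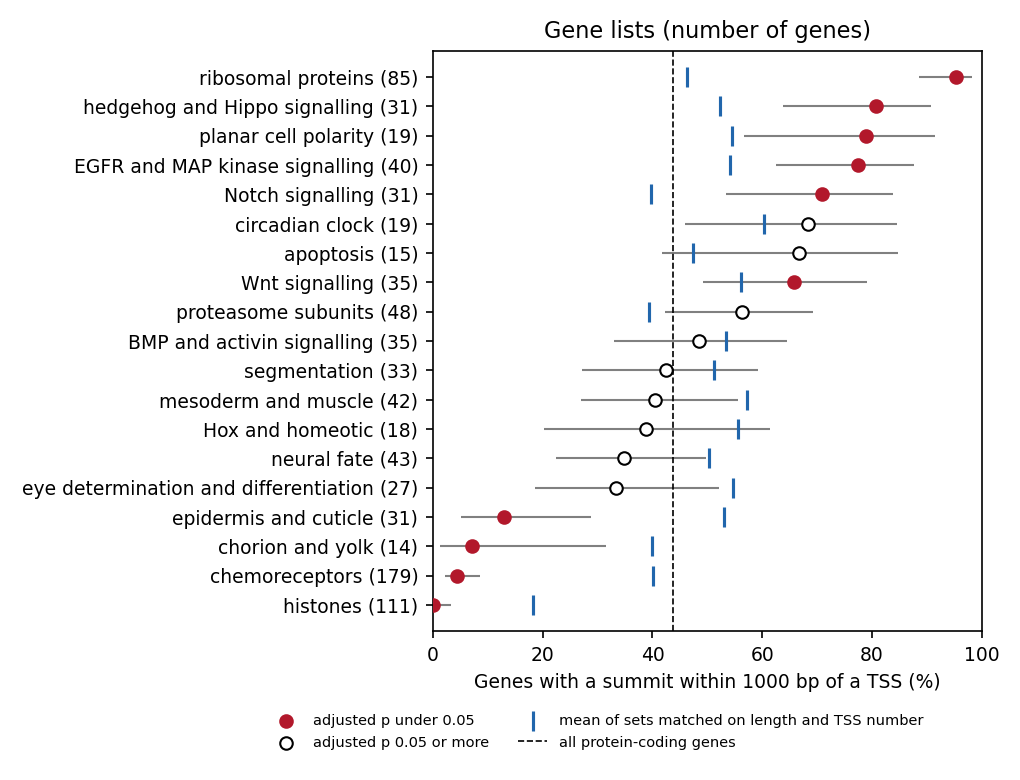
Share of genes (%) with an IDR summit within 1000 bp of a TSS for 19 gene lists, with list size in brackets, 95% Wilson intervals, the mean of gene sets matched on length and TSS number (blue bar) and the share of all protein-coding genes (dashed line, 43.8%). Ribosomal protein genes stand at 95.3% and chemoreceptor genes at 4.47%.

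Several core promoter elements of broadly expressed fly genes were more frequent at summits than 1000 bp away, each in a minority of summit windows. The DNA replication-related element (DRE), bound by DREF, was present in 10.6% of summit windows and 2.36% of paired windows 1000 bp away (ratio of discordant pairs 4.85, 95% interval 4.16 to 5.68, adjusted p = 9.2e-120, exact McNemar test). Motif 1, bound by M1BP, was at 4.43% against 0.527% (ratio 8.72, interval 6.44 to 12.1), Motif 7 at 12.9% against 6.11% and Motif 6 at 0.764% against 0.172%. Sequences of the insulator proteins CTCF (2.03% against 0.419%, ratio 5.05, interval 3.54 to 7.40) and Su(Hw) (ratio 2.48) were also more frequent. Of the 29 sequences, 12 were more and 10 less frequent at summits.

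The TCF site of the Wnt pathway did not differ (3.53% against 3.58%, exact adjusted p = 0.91), and the GC-rich Mad site of the BMP pathway was less frequent (0.946% against 2.95%, ratio 0.316, interval 0.245 to 0.404). The site of the early activator Zelda (ratio 0.539) and the Snail type E-box (0.472) were less frequent, and the TATA box (2.37) and the homeodomain core TAATTA (1.75) more frequent. Summits were AT-rich, with a mean GC content of 34.9% within 500 bp of a TSS and 30.8% farther away, against 42.0% at random positions. Against windows matched on GC content and TSS proximity the TATA box (1.05), homeodomain (0.996), Mad (1.17), Snail (0.978) and Zelda (0.75) sequences no longer passed the threshold. DRE (3.39), Motif 1 (10), Motif 7 (3.24) and CTCF (10.3) did. The Brinker site (2.16), the CAGCTG E-box (1.80) and the GAGA repeat (1.36) also passed it as more frequent, unlike against the paired window (0.897, 0.870 and 0.849). At the 3684 summits over 1000 bp from a TSS, DRE (1.08) and Motif 1 (1.07) did not differ from the paired window.

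**Figure D4:**
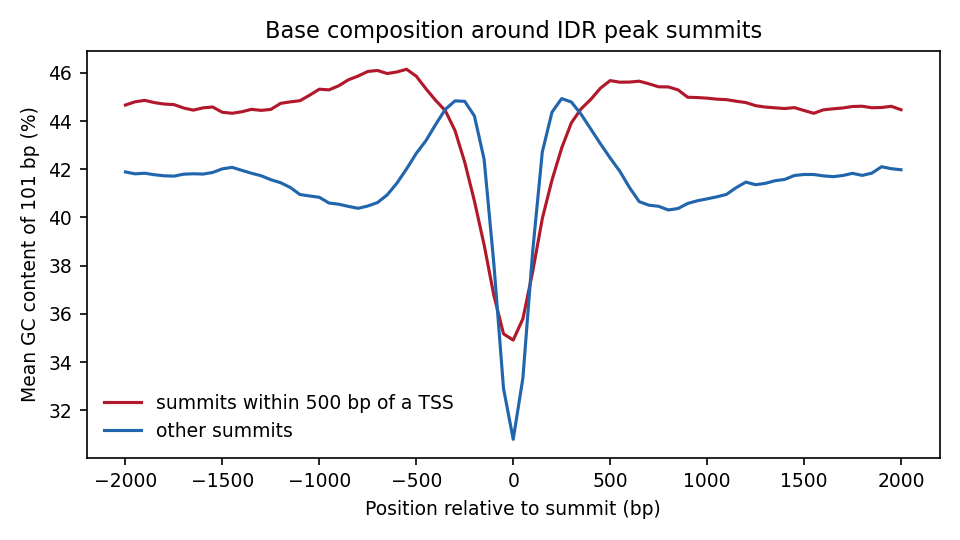
Mean GC content (%) of windows around IDR summits by position relative to the summit (bp), for summits within 500 bp of a TSS (red) and other summits (blue); the vertical axis does not start at 0. GC content dips at the summit, to 34.9% and 30.8%.

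**Figure D5:**
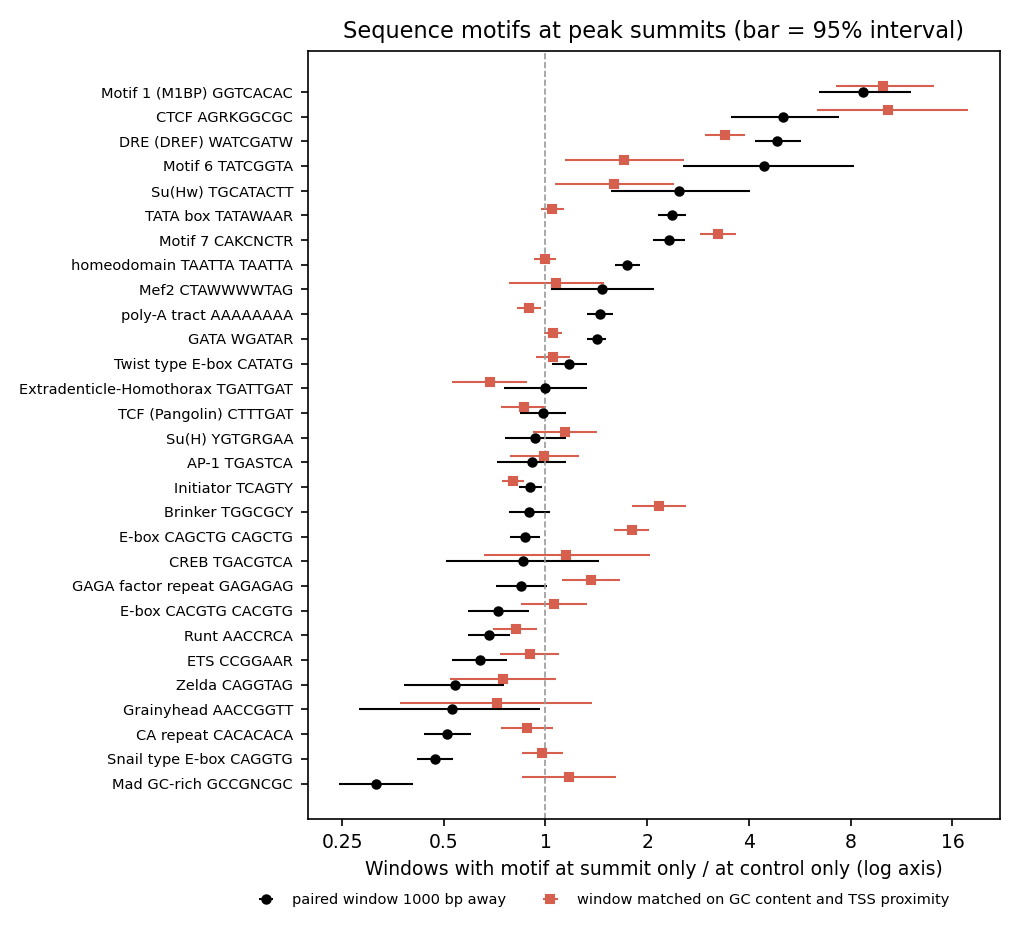
Ratio of windows with a motif at the summit only to windows with it at the control only (log axis, bars 95% intervals) for 29 consensus sequences, against a paired window 1000 bp away (black) and a window matched on GC content and TSS proximity (red). Motif 1, CTCF, DRE and Motif 7 lie above 1 with both controls.

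Genes that share a promoter region with a head-to-head neighbour had summits more often than other genes. Of 5527 such protein-coding genes 70.3% had a summit, against 26.5% of 8441 others (odds ratio 6.56, 95% interval 6.08 to 7.08, Fisher's exact test). A summit between head-to-head genes counts for both of them. Against the 1201 other genes with a neighbouring TSS within 1000 bp, of which 30.8% had a summit, the odds ratio was 5.31 (interval 4.63 to 6.10).

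The X chromosome had a slightly higher share of genes with a summit, 1032 of 2196 (47.0%), than the 4 large autosomal arms, 5068 of 11669 (43.4%, odds ratio 1.15, interval 1.05 to 1.27, p = 0.0021, Fisher's exact test). The direction turned among the 4649 strongest peaks (24.5% against 28.2%, odds ratio 0.829, interval 0.745 to 0.922, exact p = 0.00044). The small chromosome 4 had 24.5 peaks per Mb (exact Poisson interval 16.8 to 34.4) against 65.3 to 74.7 on the other chromosome arms, and the Y had no IDR peak.

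At the tagged gene itself, nmo (FBgn0011817, chromosome 3L, 7979046 to 8054147, plus strand), a peak lay at the promoter. Its summit at 7978892 was at -154 bp from the TSS, with a signal value of 1171 and rank 631 in the IDR list, 351 in replicate 2 and 852 in replicate 3. A stronger peak was in an intron (summit 7989008, signal value 1762, rank 261). Within the gene and 20 kb on each side the IDR list held 11 peaks, the 50.7th percentile of 10000 random windows of the same length with at least as many TSSs (21). The pooled list held 53, the 94.2nd percentile.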

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

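The pooled peaks that the authors' IDR threshold left out were examined in tests chosen after the data had been seen. Of these 20701 summits, 22.9% lay within 500 bp of a protein-coding TSS, above the 11.5% of random placements and below the 49.4% of the IDR list. They are listed here because the main tests of classes, motifs and gene lists in the report rest on the IDR peaks alone. The share fell with rank, from 33.3% at ranks 9300 to 15000 to 19.0% beyond rank 15000, while coding sequence rose from 0.561% to 4.70% of summits. Of the 30000 pooled peaks, 13874 (46.2%), all outside the IDR list, had a q over 0.05 by the deposited column, so the counts that follow rest in part on peaks not past that level. With all 30000, 61.8% of protein-coding genes had a summit within 1000 bp of a TSS, and 12 gene lists had a higher share in place of 6. Neural fate (36 of 43 genes, odds ratio 3.19, exact adjusted p = 0.0053), mesoderm and muscle (35 of 42, 3.10, exact adjusted p = 0.0064) and segmentation genes (28 of 33, 3.47, exact adjusted p = 0.01), which were not above other genes with the IDR list, were above them here. BMP and activin genes (28 of 35), apoptosis genes (14 of 15) and circadian clock genes (17 of 19) also passed the threshold, while chemoreceptor genes stayed low (23 of 179). No sets matched on gene length or TSS number were drawn for the pooled list, and no explanation was tested for this part.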

How the results depend on the processing

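Alternatives with windows, placements or gene sets matched on GC content, all pooled peaks for gene lists, divergent genes against close neighbours, and the chorion list without Cp190 and Cp110 were chosen after the data were examined. Over all results and alternatives 329 of 451 values were rated as kept. Among them were the promoter share (2.80 to 4.76 times random), the near absence from coding sequence, and divergent promoters (odds ratio 5.31 to 7.35). Tested values had to keep their direction and their side of the threshold, and counts to stay within 1.5 times the reported count. Replicate overlap had to stay within its Wilson interval. The share of summits within 1000 bp of a TSS had to move by less than the SD of the values of the 2 replicates alone, a lenient rule. The rank correlation over all pooled peaks was rated as changed without a rule. Replicate overlap depended on the criterion: 64.8% and 62.9% with a reciprocal overlap of 50%, 77.4% in both directions with summits within 100 bp, and 89.4% and 88.5% for the 1000 strongest peaks. The Spearman rank correlation of the replicates was 0.87 over all pooled peaks found in both replicates. Among the 4649 strongest peaks, the strength difference at promoters was no longer past the threshold (delta 0.0359, permutation p = 0.15), where selection on the compared signal value narrows it by itself, 3 gene lists were higher in place of 6 (without Wnt, planar cell polarity and Notch, odds ratios 2.22, 2.38 and 1.91, exact adjusted p = 0.052, 0.14 and 0.18), and the X share turned (odds ratio 0.829). With all pooled peaks, 46.2% of which had a q over 0.05, 12 lists were higher, and segmentation (3.47), neural fate (3.19) and mesoderm (3.10) turned; the hedgehog and Hippo odds ratio has no finite value there, since all 31 genes had a summit. Fewer peaks can make list tests weaker, but among the 4649 strongest peaks the odds ratios of the 6 higher lists fell as well. The cause of this and of the other changes in this part was not tested. Only 6 motifs were higher at summits over 1000 bp from a TSS, in place of 12, where Mef2 turned (0.958). With GC-matched windows 4 were lower in place of 10. GAGA (1.36), CAGCTG (1.80) and Brinker (2.16) turned and were past the threshold as higher, and poly-A (0.892) as lower. CACGTG (1.06), Mad (1.17) and TAATTA (0.996) turned without a call. Brinker was past the threshold as lower among the 4649 strongest peaks (0.716) and over 1000 bp from a TSS (0.72). Grainyhead turned with the window 3000 bp away (1.06). Without replicate 3 or replicate 2 the number of lower motifs was 5 and 10, GAGA 1.24 and 0.632, and CAGCTG 1.05 and 0.846. Results not past the threshold in the report also crossed a ratio of 1, in the following settings without a call. With all pooled peaks these were the eye (2.17) and Hox lists (3.10), and with a summit anywhere in the gene the eye (1.93), Hox (2.5), segmentation (1.02) and mesoderm lists (1.73). With summits within 500 bp they were BMP (0.894) and segmentation (1.12), among the 4649 strongest peaks BMP (0.658), mesoderm (1.18), TCF (1.01) and Su(H) (1.03), and with sets matched on length BMP (0.91). With sets, windows or placements matched on GC content they were segmentation (1.42), Hox (1.05), neural fate (1.02), CREB (1.15), Su(H) (1.14) and other exons (1.00). TCF crossed with the 50 bp window (1.13), the window 3000 bp away (1.07) and summits over 1000 bp from a TSS (1.01), and Su(H) with the window 3000 bp away (1.04). Extradenticle, at exactly 1 against the window 1000 bp away, was at 1.25 with the 50 bp window and 1.19 over 1000 bp from a TSS, but at 0.684 and past the threshold with GC-matched windows (adjusted p = 0.01). Without replicate 2 and without replicate 3, segmentation was at 0.594 and 1.32, Hox 0.39 and 1.24, mesoderm 0.759 and 1.24, TCF 1.04 and 0.993, Brinker 0.982 and 1.05, and Su(H) 1.02 and 0.963. Counted in the gene alone, the pooled peaks of nmo stood at the 87.4th percentile. Read depth was unknown, so its effect on weak peaks stays open.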

Other observations

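The tests of base composition, core promoter motifs, the shared 8-mer and the X chromosome were chosen after the related results had been seen; those on nmo and gene length were written before the data were examined, and that on tRNA genes after peak positions had been explored but before tRNA genes were counted, with their copy number added after. Protein-coding genes with a DRE or Motif 1 within 200 bp of a TSS had a Nemo summit in 69.6% of 3539 cases, against 35.1% of the others (odds ratio 4.24, 95% interval 3.90 to 4.60, Fisher's exact test). Motif 1 alone gave 77.2% and the DRE 67.4%. Genes with a TATA box sequence (3810 genes, 41.9%, odds ratio 0.897) or an Initiator sequence (6754 genes, 40.4%, odds ratio 0.763) in that window had summits less often than the rest. These are matches to short consensus sequences, which do not show that the element is in use. In sets matched on promoter GC content and TSS number, 49.3% of genes had a summit in place of the 69.6% (permutation p = 0.0001, the smallest the test can give). As a hypothesis found and tested on the same peaks, Nemo recovery in whole embryos may follow the promoters of broadly expressed genes.

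An 8-mer was more frequent at summits away from promoters than at control windows. On chromosomes 2L, 3L and X the 8-mer CACTGAGA was the most over-represented around summits more than 1000 bp from a TSS. On the held-out chromosomes 2R, 3R and 4 it was present in 86 of 1401 summit windows and 6 paired windows (ratio of discordant pairs 14.3, interval 6.32 to 40.1, exact p = 3.1e-19). Over all chromosomes it was in 6.43% of these summit windows, 0.380% of windows matched on GC content, and 1.57% of windows nearer to a TSS. The overlapping 8-mers CAGTGCAC and TCAGTGCA were also over-represented on the held-out chromosomes (ratios 12.3 and 7.36). No protein was assigned to this sequence.

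Most other gene types had summits less often than protein-coding genes. Transfer RNA genes were tested because short, heavily transcribed genes can give peaks in many precipitations: 66 of 290 (22.8%) had a summit within 1000 bp, against 43.8% of protein-coding genes (p = 1.9e-13, Fisher's exact test). Against the 10269 protein-coding genes with 1 TSS (36.8%) the share was also lower (odds ratio 0.505, p = 4.6e-07), but the 52 transfer RNA genes with a sequence found once in the genome did not differ detectably from these (30.8%, odds ratio 0.762, p = 0.39), nor from the 238 found in more copies (21.0%, p = 0.14, all by Fisher's exact test). Reads cannot always be placed with certainty in such copies, which the comparison fixed beforehand left out of account, so the idea stays open, and ribosomal protein genes, also heavily transcribed, stood at 95.3%. The shares were 21.0% for non-coding RNA genes, 24.9% for snoRNA genes and 6.97% for pseudogenes. Small nuclear RNA genes, at 11 of 32 (34.4%), did not differ detectably from protein-coding genes (exact p = 0.37). None of 99 rRNA genes had a summit, in repeats where reads cannot be placed with certainty. Transposable elements held 28 summits (0.301%, against 5.94% of random positions). Random positions were drawn without regard to whether reads can be placed there, so this gap need not be a depletion. Of the 6 gene lists with a higher share, 5 had an unadjusted permutation p under 0.05 against sets matched on gene length and TSS number, and 4 after adjustment. Gene length and TSS number, with 3 or more TSSs taken as 1 class, do not account for most of them. Differences in TSS number above 3 and head-to-head neighbours were not matched, so their part stays open.

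The base composition at summits was low in GC, with a mean of 32.9% ± 9.68 (SD) in the window of 50 bp on each side, against 42.0% at random positions, and 27.7% at the 1000 strongest. A preference for AT-rich fragments alone is argued against by the promoter share, which stayed 4.3 times that of random positions matched on GC content. Nor does it account for the missing coding summits, since GC-matched positions fell in coding sequence 53.1 times as often as the observed ones. The DRE was in 10.6% of summit windows against 3.42% of windows matched on GC content and TSS proximity (ratio of discordant pairs 3.39). Precipitation of open chromatin whatever the tag could give such a pattern, and stays open because no mock precipitation was analysed here; no biological explanation was tested.

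The tagged gene nmo could carry extra peaks if the transgene adds copies of the locus. Its region of 20 kb on each side held 53 pooled peaks, the 94.2nd percentile of random windows with at least as many TSSs. The replicates differed, with 62 peaks in replicate 2 (97.6th percentile) and 40 in replicate 3 (80.7th), and the IDR list stood at the 50.7th. Extra copies and ordinary variation between regions cannot be told apart, because a single locus gives 1 value and the copy number was not measured.

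Genes on the X were fewer among the strongest peaks, and its lower copy number in a mixed-sex sample could lower all X peaks by 1 factor. With equal numbers of each sex and a signal value proportional to copy number, this would be a log2 shift of -0.42. The scale of the signal value is unknown, so the true size of such a shift is unknown as well. The signal value reached by the top 5% of X genes was lower than that of autosomal genes by a log2 difference of -0.22 (95% bootstrap interval -0.37 to -0.07), and at the top 20% by -0.16. At the top 40% it was 0.10 (-0.01 to 0.20) and at the top 50% 0.53 (0.35 to 0.71). The top 50% value rests on pooled peaks below the weakest IDR peak (signal values 145 and 100, against 166). The top 40% value (212 and 198) does not, and it argues against 1 factor with a shift of -0.42 at every strength as the only difference. It cannot exclude such a factor together with a higher share of X genes with a summit (47.0% against 43.4%), because these values depend on both. A lower ceiling of strong peaks on the X stays open, and no biological explanation was tested.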
